A study of Homo sapiens with 6 samples.

How the data were processed

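Gene expression was measured in cultured HMEC endothelial cells kept for 6 h in medium with exosomes from the same kind of cell, with such exosomes depleted of the microRNA miR-214, or with no exosomes. Exosomes are small vesicles that cells release. There were 3 groups of 2 samples. Per the labels, total RNA was amplified and labelled with Cy3 or Cy5, and each sample is 1 channel of a 2-colour Agilent array. Replicate 1 of the miR-214-low group and replicate 2 of the no-exosome group carried Cy5, and the other 4 samples carried Cy3.

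The deposited scanner files hold the intensity of each spot and of its local background, made with Agilent Feature Extraction 10.7.3.1 per the file headers. Their processed signal is an intensity that was background-subtracted and dye-normalized by the same program, per the file headers. The deposited table of the whole series holds the authors' normalized intensity on a linear scale, and its normalization and centring are not given in the sources used here. Its columns had medians between 136.4 and 138.8, and each followed the background-subtracted intensity of its own sample's channel with a rank correlation that rounds to 0.999 or 1. The files also hold annotation columns of another kind (names and flags), as deposited.

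The 6 samples lay on 5 arrays of 2 slides. Replicate 1 of the miR-214-low group and replicate 1 of the control group were the 2 channels of 1 array. Both exosome groups were on slide 1 and both no-exosome samples on slide 2, so slide and group cannot be told apart in comparisons with no exosomes. On the other 4 arrays the second channel, 4 channels in all, was not used here. The number of arrays limits the precision. Between 69.4% and 76.1% of spots were well above background, and no spot was saturated.

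Each sample's own channel was corrected with normexp (offset 50) over all 45015 spots. Control spots and spots flagged as non-uniform or as population outliers were then left out, and log2 intensities were quantile normalized over the 6 samples. Spots of 1 probe were averaged. Of 41000 probes, 62 lacked a usable value in some sample and 11521 were not well above background in both samples of any group, which left 29417. Gene names came from the accession in the files, matched to a RefSeq table of assembly GRCh38.p14 that was used for names only. This matched 20295 tested probes, a further 1128 matched by symbol and 314 by an older symbol, and 7680 kept the files' name. Probe positions are those in the files (hg19). A gene was represented by its brightest tested probe, which gave 14217 genes.

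Differences were tested with limma 3.58.1, two-sided, with group and dye as terms and all 6 samples sharing 1 estimate of the spread (2 residual degrees of freedom). The samples of the shared array had a common correlation of 0.06, estimated by restricted likelihood. Benjamini-Hochberg adjustment ran over the probes with a threshold of 0.05. Differences are given on the log2 scale with the standard error of the fit. Gene lists, 25 in number, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. P-values were adjusted over the lists of each comparison. With an estimated correlation, camera rests on the 2 residual degrees of freedom, so hardly any list could pass. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison, the 12 genes in each direction that passed, filled where fewer passed by the smallest unadjusted p in that direction, together with ATM and up to 4 members of each list. X-inactivation and Y-linked genes, clones and uncharacterised loci were not named.

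The fit was tested on simulated data with the real design, dye effects and fitted spread of each probe, the spread being set equal in all 6 samples. In the comparison of miR-214-low with control exosomes it called 82.4% of simulated changes of 1 log2 and 97.3% of those of 2 log2, among 29417 probes with 200 changed. False calls made up 6.05% of all calls there. In the real data the replicate pairs differed in spread, and changes of 4 log2 were simulated among the others. These shares may therefore not hold for the real data. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Alternatives covered the dye term, the shared array, the replicate number as a block, the samples used, background correction, normalization, the authors' table, the filter on dim probes, the variance model, the probe of a gene and each sample left out. A trend with probe GC content and a count of the control pair as 1 sample were added after the data were seen. A test of miR-214 seed sites in 3' untranslated regions was not run, since no such sequences were used here.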

Results

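Responses of HMEC endothelial cells after 6 h were compared among cells given control exosomes, cells given exosomes depleted of miR-214, and cells given no exosomes, with 2 samples per group. Median spot intensities before normalization lay between 83.5 and 286.7, the 2 highest being the Cy5 samples. Replicates of the same group were not equally alike. Over all tested probes, the standard deviation of the log2 difference between replicates was 0.10 for control exosomes, 0.27 for miR-214-low exosomes and 0.33 for no exosomes. On 221 probes with several spots, the control samples differed at the same spot by 0.06 (scaled median absolute deviation, log2), which was less than the 0.12 and 0.14 between spots of 1 probe within those arrays. The corresponding value was 0.30 for the miR-214-low pair and 0.28 for the no-exosome pair. The control samples differed by less than the noise between spots within an array, which also holds position effects, and they are given below by their single values rather than as a mean with an SD. An analysis that counted them as 1 sample is given where counts are compared.

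The first comparison asked whether depleting exosomes of miR-214 alters the response of recipient cells. ATM, the kinase that signals DNA breaks and a reported miR-214 target, measured 7.73 and 8.14 in the miR-214-low samples and 7.14 and 7.18 in the control samples on its brighter probe (chromosome 11, 108236085 to 108236144). The difference was 0.89 ± 0.13 log2 (SE, n = 2 per group), higher with miR-214-low exosomes, and did not pass over all probes (limma adjusted p = 0.98). It passed when adjusted over the list alone, both among 22 measured ATM and DNA damage genes (limma adjusted p = 0.0391) and among 25 measured reported miR-214 targets (limma adjusted p = 0.0445), the only member of either list to do so. These are not separate results, since both rest on the same unadjusted p of 1 gene. They carry no adjustment over the 25 lists and count the control pair as 2 samples. The other targets mostly went the other way, with 16 of the 25 lower with miR-214-low exosomes (median −0.09 log2, camera adjusted p = 0.453, adjusted p = 0.643 with an estimated correlation), among them QKI, an RNA-binding protein, at −0.31 ± 0.09 log2. The other ATM probe (chromosome 11, 108159737 to 108159796) was nearly as bright over all samples, and brighter in the control samples, at 7.68 and 7.87. It gave −0.11 ± 0.31 log2, so the results for ATM within the lists rest on a close choice between probes. CYP1B1, a cytochrome P450 that oxidises oestrogens and xenobiotics, gave 0.91 ± 0.09 log2 (0.55 without the dye term), and BMAL2, a circadian transcription factor, gave 0.99 ± 0.14 log2, although 2 further BMAL2 probes went the other way.

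**Figure D1:**
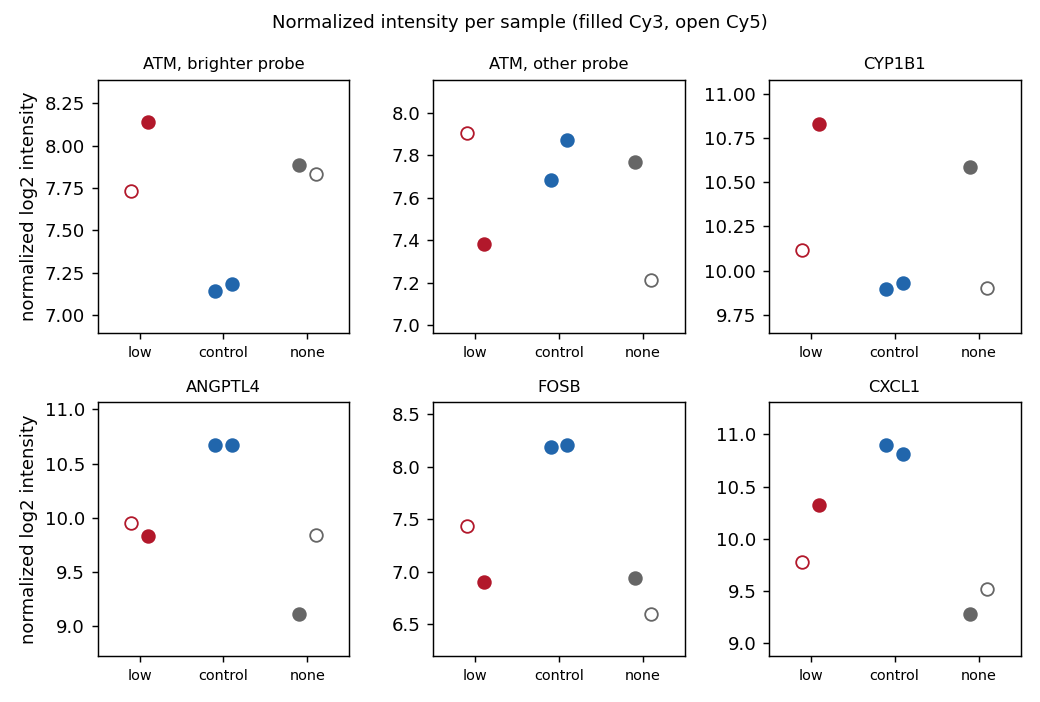
Normalized log2 intensity of each sample for 5 genes, with the brighter and the other probe of ATM in separate panels. Points are single samples of the miR-214-low, control and no-exosome groups, filled for Cy3 and open for Cy5. On the brighter ATM probe the control samples, at 7.14 and 7.18, lie below the other 4.

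Among the values with the smallest unadjusted p in the lower direction were ANGPTL4, a secreted regulator of lipoprotein lipase (−0.998 ± 0.185 log2), ETV5, an ETS transcription factor (−0.67 ± 0.11 log2), TLR4, the endotoxin receptor (−0.52 ± 0.09 log2), and PARP10, a mono-ADP-ribosyltransferase (−0.71 ± 0.10 log2, but −0.37 without the dye term and −0.08 ± 0.10 on its other probe). None of these passed over all probes (limma adjusted p = 0.98 for each). GRM5P1 gave −0.86 ± 0.09 log2 and did not pass either (limma adjusted p = 0.98). It was not well above background in either miR-214-low sample, at 6.40 and 6.08. Those values lay above the dimmest probe above background in the same samples, at 5.98 and 6.02. The plain difference of the group means was 1.60-fold, higher with control exosomes, and is an estimate rather than a lower limit. In all, limma called 0 of 29417 probes, against 886 at an unadjusted p under 0.05 where chance gives 1471. With the control pair counted as 1 sample the count was also 0.

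With camera's preset correlation, 7 of the 25 lists passed. Angiogenesis and tip cell genes were lower with miR-214-low exosomes (median −0.14 log2, 23 of 31 lower, limma camera adjusted p = 0.00288, adjusted p = 0.496 with an estimated correlation), with ANGPTL4 as above, PGF at −0.32 ± 0.09 log2 and VEGFA at −0.48 ± 0.19 log2 on the brightest of its 4 probes, the other 3 giving −0.12 to 0.05 log2. Endothelial identity genes were also lower (median −0.13 log2, 20 of 25, camera adjusted p = 0.00339, adjusted p = 0.496 with an estimated correlation), FLI1 at −0.53 ± 0.11 log2 and ROBO4 at −0.25 ± 0.12 log2. So were NRF2 and metal response genes (13 of 19, camera adjusted p = 0.0332), where HMOX1 gave −0.54 ± 0.18 log2 (−0.35 without the dye term), genes of the unfolded protein response (16 of 22, camera adjusted p = 0.0368), and extracellular matrix genes (19 of 24, camera adjusted p = 0.0423). With an estimated correlation these 3 had adjusted p = 0.496, 0.496 and 0.640. Mitosis genes were higher (20 of 24, camera adjusted p = 0.0106), with TOP2A at 0.28 ± 0.10 log2 (0.18 without the dye term), as were ribosomal protein genes (18 of 22, camera adjusted p = 0.0196). No list passed with an estimated correlation (smallest adjusted p = 0.496, shared by these 2), and fry gave 0 lists at an unadjusted p under 0.05. With 2 residual degrees of freedom the former test could hardly pass any list. Its failure therefore does not show that correlation between genes produced the calls. Endothelial identity, mitosis and NRF2 genes had estimated correlations of −0.03, −0.02 and −0.04, below the preset 0.01. The other called lists lay above it, at 0.12 for matrix, 0.05 for angiogenesis, 0.03 for ribosomal protein and 0.02 for unfolded protein genes. These estimates also rest on the 2 residual degrees of freedom. The calls on these 7 lists still rest on the preset correlation. In none of these lists did a member pass over all probes. Without replicate 2 of the miR-214-low group the dye term rests on the no-exosome pair alone, whose replicate difference is then removed as dye. Replicate 1 itself lay below both control samples in the median deviation from the mean of all samples. For angiogenesis genes it was at 0.04 against 0.10 and 0.13 log2. Unfolded protein genes gave 0.01 against 0.09 and 0.07 log2, and matrix genes 0.06 against 0.10 and 0.10 log2. Leaving out replicate 2 turned the mean shift to 0.01 log2 for angiogenesis, 0.05 log2 for unfolded protein and 0.24 log2 for matrix genes. It also ended the calls on ribosomal protein genes (camera adjusted p = 0.856, mean shift 0.02 log2 from 0.11) and endothelial identity genes (0.953, −0.13 from −0.20), and that on NRF2 genes although their mean shift stayed (0.438, −0.12 from −0.11), and moved VEGFA to −0.01 log2, HMOX1 to −0.10 log2, TOP2A to 0.15 log2, FLI1 to −0.33 log2 and ROBO4 to −0.48 log2. Mitosis and NRF2 genes did not pass without replicate 1 of the miR-214-low group or without either no-exosome sample (camera adjusted p = 0.226 and 0.187, mean shifts 0.06 log2 from 0.09 and −0.10 from −0.11), nor unfolded protein genes without either control sample (0.0517 and 0.0561, −0.09 each as with all samples). The matrix and unfolded protein shifts were larger, −0.31 and −0.13 log2 from −0.16 and −0.09, without miR-214-low replicate 1 or either no-exosome sample, and the mitosis shift was 0.18 log2 without miR-214-low replicate 2. Of 25 alternatives, the NRF2 call was lost in 11, unfolded protein in 9, mitosis in 8, ribosomal protein in 5 and matrix in 4. Not all of these alternatives are separate. Only the Cy3 samples, the groups compared or the exosome slide gave the same fit as omitting miR-214-low replicate 1 or either no-exosome sample. In that fit the difference rests on miR-214-low replicate 2 beside the control pair. The remaining 18 lists, the reported miR-214 targets among them, had camera adjusted p between 0.0552 and 0.99.

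Cells given control exosomes were next compared with cells given none, a comparison that also separates slides 1 and 2. FOSB, an AP-1 subunit, was 1.47 ± 0.25 log2 higher with control exosomes, ANGPTL4 1.41 ± 0.19 log2, the neutrophil chemokine CXCL1 1.38 ± 0.23 log2 (0.79 without no-exosome replicate 1), and NPPB, which encodes the B-type natriuretic peptide precursor, 0.59 ± 0.09 log2. None passed over all probes (limma adjusted p = 0.585 for each). ATM gave −0.81 ± 0.13 log2, CYP1B1 −0.68 ± 0.09 log2 (−0.32 without the dye term), and MYO1C, an unconventional myosin, −0.92 ± 0.10 log2 on its brighter probe and 0.17 ± 0.16 log2 on the other. The other ATM probe gave 0.27 ± 0.31 log2. EGR1, an immediate early transcription factor, gave −1.87 ± 0.36 log2, so members of the immediate early list went both ways, and 3 of its 24 passed when adjusted over the list alone (smallest limma adjusted p = 0.044). ANGPTL4 passed in the angiogenesis list alone (limma adjusted p = 0.0394). limma called 0 probes, with 2460 at an unadjusted p under 0.05.

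In that comparison 3 lists passed with the preset correlation. Interferon response genes were lower with control exosomes (median −0.30 log2, 21 of 22 lower, camera adjusted p = 0.000764, adjusted p = 0.914 with an estimated correlation), IFIT1 at −0.52 ± 0.14 log2. Angiogenesis genes were higher (23 of 31, camera adjusted p = 0.0118), VEGFA at 0.80 ± 0.19 log2 on its brightest probe (0.01 to 0.24 log2 on the other 3), and NRF2 and metal response genes were higher (14 of 19, camera adjusted p = 0.0177), HMOX1 at 0.78 ± 0.18 log2. None passed with an estimated correlation (smallest camera adjusted p = 0.814), where hardly any list could. The estimated correlation of the interferon list was high, at 0.70. With fry, 2 lists had an unadjusted p under 0.05, of which none passed (smallest adjusted p = 0.147). Without no-exosome replicate 1 the NRF2 list did not pass (camera adjusted p = 0.295) although its mean shift stayed, at 0.20 log2 from 0.21. The mean shift of the angiogenesis list was then 0.42 log2 from 0.23 and that of the interferon list −1.04 log2 from −0.37. EGR1 moved to −2.85 log2, IFIT1 to −0.82 log2, VEGFA to 1.29 log2 and HMOX1 to 1.23 log2. In that fit the dye term rests on the miR-214-low pair alone, whose replicate difference is then removed as dye. EGR1 itself measured 8.93 and 8.96 in the control samples, against 10.50 and 10.62 with no exosomes. These shifts, and the CXCL1 value above, therefore include the replicate difference of the miR-214-low pair. The interferon shift was −0.15 log2 without no-exosome replicate 2 or either miR-214-low sample. The interferon genes were highest in no-exosome replicate 2 and next in miR-214-low replicate 2. Their median deviation from the mean of all samples was 0.37 log2 in replicate 2 of the no-exosome group and −0.08 log2 in replicate 1. It was 0.18 and −0.16 log2 in replicates 2 and 1 of the miR-214-low group, and −0.18 and −0.20 log2 in the control samples.

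Cells given miR-214-low exosomes were compared with cells given none in the same way. NPPB was 0.50 ± 0.08 log2 higher, NABP1, a single-stranded DNA binding protein, 0.48 ± 0.08 log2, and SERPINB2, a plasminogen activator inhibitor, 0.48 ± 0.10 log2. In the other direction SRCIN1, an inhibitor of Src kinase, gave −1.15 ± 0.11 log2, and ORC6, a subunit of the origin recognition complex, −0.90 ± 0.12 log2 on its brighter probe, against −0.00 ± 0.08 log2 on the other. SOX18, an endothelial transcription factor, gave −1.35 ± 0.42 log2, which came mainly from no-exosome replicate 2, at 10.65 beside 8.61 in replicate 1 and 8.46 and 8.11 with miR-214-low exosomes. It was −0.50 log2 without that sample or miR-214-low replicate 1, and −2.19 log2 without either of the other 2. limma called 0 probes (smallest adjusted p = 0.724), with 2001 at an unadjusted p under 0.05. ATM differed by 0.08 ± 0.12 log2, −0.09 without miR-214-low replicate 2 or no-exosome replicate 1 and 0.25 without either of the other 2. Interferon response genes were lower (19 of 22, camera adjusted p = 0.00971) and ribosomal protein genes higher (19 of 22, camera adjusted p = 0.045). Neither passed with an estimated correlation (camera adjusted p = 0.822 and 0.703), where hardly any list could. fry gave 4 lists at an unadjusted p under 0.05, of which none passed (smallest adjusted p = 0.0980). Of 24 alternatives, some of which reduce to the same fit, the ribosomal call was lost in 8. The interferon call was lost in 1 and reversed in 3. Without miR-214-low replicate 2 or no-exosome replicate 1 the ribosomal list did not pass (camera adjusted p = 0.571, mean shift 0.05 log2 from 0.11), and the interferon shift was −0.65 log2 from −0.20. Without replicate 2 of the no-exosome group, or without replicate 1 of the miR-214-low group, the interferon list passed in the other direction (mean shift 0.24 log2, camera adjusted p = 0.00692), and the ribosomal shift was 0.17 log2.

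No probe was called in both comparisons with no exosomes. Across 29417 probes, which are not independent replicates, the fold changes of the 2 comparisons correlated with r = 0.714, where unchanged groups sharing the same no-exosome samples gave 0.459 on average over 100 simulated sets. Their covariance was 0.0385 against a simulated 0.0116. The simulated sets gave every sample the same spread. In the data the shared no-exosome pair had the largest replicate SD, 0.33 log2 against 0.10 for control and 0.27 for miR-214-low exosomes. A noisier shared group raises both values, so the simulated ones are too low a reference and the excess cannot be sized. The no-exosome group has too few samples to split, so the excess may come from the shared samples, their larger spread and the slide. An effect common to both exosome groups cannot be told apart from these here. Counts in the 3 comparisons depended on which samples supplied the spread. Leaving out any 1 of the 4 samples outside the control group left the control pair as the only source of spread, and between 6855 and 9672 probes were then called between the exosome groups, whereas leaving out either control sample gave 0.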

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

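The GC trend and the control pair counted as 1 sample were tried only after the data were seen. The 3 counts of changed probes and the overlap stayed at 0 without the dye term, with the shared array as independent or as a fixed term, without background correction, with offset 0, median scaling, processed signals, the authors' table, other filters, a trended robust variance, 1 probe per gene, the GC trend removed and the control pair as 1 sample. Replicate numbers occur once in each group and were not taken to pair the samples, since not every correlation of replicate differences was clearly above 0 (miR-214-low with control 0.135, miR-214-low with no exosomes 0.442, control with no exosomes −0.0238). With the replicate block beside the dye term the counts and the overlap were 0 and the list calls 21. Where the control pair alone supplied the spread, lone samples are assumed to vary like it. Only the Cy3 samples then gave 9672 calls between the exosome groups, 4390 for control against none, 6740 for miR-214-low against none and an overlap of 1440. Only the groups compared gave 9672, 4390 and 0, and only the exosome slide 9672. Leaving out 1 sample at a time, in the order of the comparisons, gave 0 to 9672, 0 to 15544 and 0 to 13412 calls, an overlap of 0 to 11930 and 17 to 29 list calls. The 12 list calls became 20 with the array as a fixed term, 29 with Cy3 samples only, 23 with only the groups compared, 7 with offset 0, 19 with the control pair as 1 sample and 0 with an estimated correlation; the cause was not tested. Mean shifts that reversed were those of the interferon list in miR-214-low against none (0.24 with only Cy3 samples and without miR-214-low replicate 1 or no-exosome replicate 2; range without 1 sample −0.651 to 0.242) and, without miR-214-low replicate 2, of 3 lists between the exosome groups (ranges without 1 sample: angiogenesis −0.234 to 0.0141, unfolded protein −0.134 to 0.0451, matrix −0.306 to 0.242). For those 3 lists the dye term then rested on the no-exosome pair alone. ATM in miR-214-low against none ranged from −0.0947 to 0.254 log2, negative without miR-214-low replicate 2 or no-exosome replicate 1. Of 1720 values of ATM and the genes named for their p, 1277 kept direction and side of the threshold, 441 passed it and 2 reversed. Of 6569 values of the named list members, 5528 kept both, 968 passed it and 73 reversed. With processed signals ATM moved to 1.36 log2 between the exosome groups and, for control against none, to −1.26 log2, FOSB there to 2.32 and NPPB to 1.07 log2, NPPB in miR-214-low against none to 0.89 log2 and GRM5P1 between the exosome groups to −3.54 log2. The counts over 1720 and 6569 values take alternatives that reduce to the same fit as separate ones. Slide as a block could not be fitted against no exosomes, and the seed-site test was not run. Probes below background limit what dim genes can show.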

Other observations

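The tests on probe GC content were set before their results were seen, and the tests on dye, on chance and on the second ATM probe after. In the miR-214-low group and in the no-exosome group, replicate 2 lay above replicate 1 in inflammatory and immediate early genes among others, and the control samples did not differ in this way. CCL2, a monocyte chemokine, was 1.98 log2 above replicate 1 in the miR-214-low pair and 1.61 log2 above it in the no-exosome pair, and differed by −0.01 log2 between the control samples. IFITM1, an interferon-induced membrane protein, differed by 1.41, 2.30 and 0.00 log2 in the same order, ICAM1, a leukocyte adhesion molecule, by 1.08, 1.02 and −0.04 log2, and FOS by 1.32, 1.03 and 0.12 log2.

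As lists, NF-kB and endothelial activation genes were higher in replicate 2 by a median of 0.46 log2 in the miR-214-low pair (18 of 19) and 0.45 log2 in the no-exosome pair (19 of 19), against −0.03 log2 in the control pair. Immediate early genes gave 0.37 (23 of 24 higher), 0.39 (20 of 24) and 0.01 log2 (15 of 24). Interferon genes gave 0.33 (21 of 22), 0.44 (21 of 22) and 0.02 log2 (14 of 22). FOSB, an immediate early gene, went the other way, by −0.53 and −0.34 log2 in the miR-214-low and no-exosome pairs. Against the control samples the lists differed. Interferon genes were highest in these 2 samples, with a median deviation from the mean of all samples of 0.18 and 0.37 log2 against −0.08 log2 or lower in the other 4. NF-kB genes in no-exosome replicate 2, at 0.02 log2, were level with the control samples, at 0.02 and −0.00 log2, and it was replicate 1 that lay low, at −0.28 log2. In the miR-214-low and no-exosome pairs each median lay above all of 10000 random lists matched on intensity. The random lists drew genes independently, whereas the estimated correlation was 0.78 for NF-kB, 0.70 for interferon and 0.69 for immediate early genes. Lists of genes that vary together exceed such draws more easily, so these ranks do not measure how unusual the split is. The split was not particular to these lists. Of all 25, tested in the same way after these 3 were seen, p53 target genes were also higher in replicate 2 in both pairs (0.24 and 0.21 log2), and 4 lists were lower in both, sterol and lipid synthesis (−0.21 and −0.28 log2), TGF-beta, BMP and YAP targets (−0.20 and −0.29 log2), extracellular matrix (−0.21 and −0.21 log2) and angiogenesis genes (−0.12 and −0.10 log2). At most 1.16% of random lists lay below any of these 4 in either pair, and at least 99.91% lay below the p53 list. Matrix and angiogenesis genes were also called lower with miR-214-low than with control exosomes, so that difference and the replicate split involve the same lists. A dye effect would have opposite signs in these pairs, since the dyes were swapped, but the smaller interferon median was 0.329 log2. Removing each sample's trend with probe GC left 0.319 log2 in the miR-214-low pair. The split runs within groups, so no biological explanation was tested, and a difference in culture, handling or RNA between the replicates of these 2 groups remains open.

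No-exosome replicate 2 was the sample farthest from the rest, and the first principal component, with 62.8% of the variance, mainly set it apart. The GC trend took away 6.06% of the variance between the no-exosome replicates, which argues against GC content as the main source. Cy5 minus Cy3 correlated at −0.442 over probes between the miR-214-low and no-exosome pairs, which argues against dye as the main source. It is the correlation of replicate 2 minus 1 with its sign turned. The shared replicate split therefore weighs on it, and a smaller part from dye is not excluded. This sample also had the most spots flagged as non-uniform or as population outliers, 111 against 48 to 63 in the others. Whether its RNA or its array differs cannot be separated with 1 sample, and no biological explanation was tested.

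The brighter ATM probe was lower in both control samples than in all 4 other samples. Dye is argued against, since the lower of the 2 Cy3 samples outside the control group lay 0.70 log2 above the higher control sample. A change of every ATM transcript stays open, because the other probe's 95% interval reached 0.717 log2, above the first probe's lower bound of 0.54 log2. Chance among many probes also stays open and may account for it, since the difference did not pass over all probes. In the test of chance, 15 tested probes reached ATM's unadjusted p where uniform p-values give 50.1. That count cannot decide, because small p-values were too few throughout this comparison, with 886 under 0.05 where uniform ones give 1471. ATM was, however, named before the data were examined. A difference caused by miR-214 in control exosomes is a hypothesis that the comparison of 2 such alike control samples does not settle.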
